A study of Mus musculus with 12 samples.

How the data were processed

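RNA sequencing measured the transcripts of mouse cerebral cortex and hippocampus, per the labels from total RNA of C57BL/6 mice extracted with Trizol. The 12 libraries fall into 4 groups of 3, cortex and hippocampus from wild-type mice and from mice labelled mTert KO (G1), called knockout here. Nothing in the labels says that the 3 libraries of a group came from separate animals, so every p-value measures the spread between these samples, which may be technical in part. Library strandedness, read length, age of the mice and sequencing batch are not given in the sources used here.

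The authors deposited 1 table per tissue with 55487 gene rows, and the values are a signal that the table names call normalized counts. STAR, HTSeq, DESeq2 and the genome build GRCm38 are named in the submitters' processing notes, with versions and settings not given in the sources used here. Within each library all deposited values were whole multiples of 1 step (100% of values within 0.001 of a whole number), as gene read counts divided by 1 size factor per library would be. The steps lay between 0.902 and 1.07. The values divided by their step sum to between 68424934 and 77972013 reads per cortex library and between 72401909 and 86639113 per hippocampus library, taking 1 step as 1 read, so counting error was small for all but the least expressed genes. For cortex wild-type libraries 1 and 2 that reading of the step could not be checked, and their totals are estimates. A value of 0 allows up to 3 reads, a floor that covers counting error only. The tables were scaled separately, so levels were compared within a tissue only. Columns of other samples numbered 0.

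Gene identifiers were matched to the GENCODE mouse annotation of the same build; 55227 of the 55487 rows matched and 260 did not. Symbols, coordinates, gene classes and exonic lengths come from that annotation. Exonic length is the length of all annotated exons of a gene merged. How reads were assigned to genes that overlap is not given in the sources used here, so genes that overlap another gene, on either strand, or that have a second gene model of the same name are called uncertain or given with the overlap.

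Genotypes were compared within each tissue with limma 3.58.1 in R 4.3.3, with a prior variance that follows expression, on log2(normalized count + 1), for genes with a mean of at least 10 normalized counts over the 6 libraries. Fold changes are on that scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and "rose", "fell" and "changed" are used of called genes and of lists that passed their test. The difference between the tissues in the knockout effect was tested with the interaction term of 1 limma fit over the 12 libraries. That fit took cortex and hippocampus libraries as independent, although whether they share animals is not given in the sources used here. The 38 gene lists, with 899 distinct genes of which 3 were not found, were fixed before the data were examined. They cover pathways tied to telomerase and to brain function, and markers of the cell types and neighbouring brain regions that a dissection could hold. Lists were tested against all other genes with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 38 lists, and again with a correlation estimated per list. With the estimated correlation 0 lists passed in either tissue, against 5 in cortex and 2 in hippocampus at an unadjusted p under 0.05. The directional test fry passed 8 and 10 lists.

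The named genes followed a rule fixed before the data were examined. It takes Tert and App in each tissue. It adds the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose mean was at least 50 normalized counts. It further takes up to 3 members of each list with the smallest p, called genes near Tert, and the 5 genes with the smallest p for the interaction. Predicted genes without a proper name were passed over and counted only. Genes named outside this rule are said to be so.

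The fits were tested on simulated data with 200 changed genes drawn at the real means and depths. In simulated cortex, with 21948 genes, 75% of the genes changed by 1 and 41% of those changed by 0.5 on the log2 scale were called, and 4.92% of calls were false. In simulated hippocampus, with 22335 genes, these shares were 78%, 61% and 0.714%. For the interaction, with 21012 genes, they were 68%, 33% and 3.81%. In these simulations no library stood apart, as cortex wild-type library 2 did in the real data, and none carried a trend along gene length. The shares may therefore not hold for the real calls. The list test recovered 2 of 2 shifted lists in each tissue and passed 0 of 36 others. The simulated genes varied independently of each other, so this does not give the false rate for lists whose genes move together. Regroupings of the real libraries passed up to 17 lists in cortex and 21 in hippocampus.

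Alternatives covered the pseudocount, the filter, the variance model, library weights, scaling, the replicate number as a block, a joint fit of both tissues, leaving out each library, and removal of trends along gene length and GC content. On reads recovered from the hippocampus table, edgeR 4.0.16 and DESeq2 1.42.0 were run as alternatives. They were left out for cortex because the steps of wild-type libraries 1 and 2, at 0.991 and 1.00, lay too near 1 for the recovery to be checked. Plots were drawn with matplotlib 3.10.9.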

Results

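Brain tissue of wild-type mice and of mice lacking Tert, the catalytic subunit of telomerase, was profiled to find which transcripts differ without the gene. Cortex and hippocampus each gave 3 wild-type and 3 knockout libraries. Genes with a mean of at least 10 normalized counts numbered 21945 in cortex and 22337 in hippocampus. Values are means ± SD with n = 3 unless stated, log2 fold changes are knockout over wild type ± SE, and adjusted p-values are from limma.

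Tert was measured in each library first, as the targeted gene (ENSMUSG00000021611, chromosome 13, 73626911 to 73649843, plus strand, GRCm38). In wild-type cortex it reached 206, 105 and 241 normalized counts (184 ± 70.6), and in knockout cortex 0 in each of the 3 libraries, at least 60.5-fold lower when each knockout library is set to the floor of 3 reads. In wild-type hippocampus it reached 147, 184 and 128 normalized counts (153 ± 28.6). The knockout hippocampus libraries held 0, 6.31 and 0, where 6.31 corresponds to 7 reads in library 2. Tert fell in both tissues (adjusted p = 0.00116 in cortex and 0.000972 in hippocampus), so the 12 libraries carried the Tert levels that their labels name, apart from those 7 reads.

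**Figure D1:**
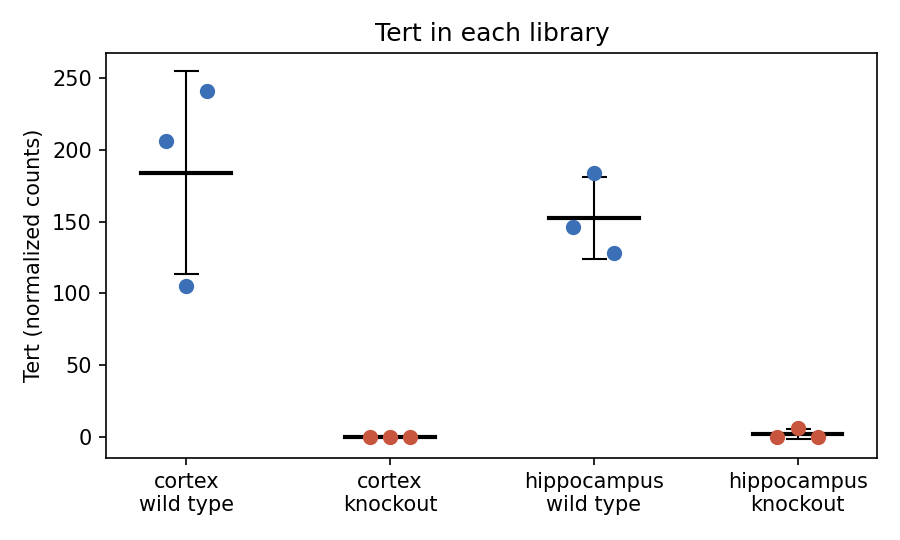
Tert in normalized counts (vertical axis) for each library of the 4 groups (horizontal axis), points for libraries, thick bars for means and whiskers for SD (n = 3). The 6 wild-type libraries lie between 105 and 241, and the knockout libraries at 0 except hippocampus library 2 at 6.31.

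App, which encodes the amyloid precursor protein (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766, minus strand), was the other gene fixed in advance. In hippocampus it rose from 101838 ± 4857 to 128266 ± 1205 normalized counts, by 0.33 ± 0.05 on the log2 scale (adjusted p = 0.00328), higher in 3 of 3 knockout libraries; with the trend along exonic length removed the value was 0.69, and over all alternatives it ranged from 0.25 to 0.69. In cortex it measured 105530 ± 6872 in wild type and 134207 ± 1294 in knockout, a log2 fold change of 0.35 ± 0.07 that missed the threshold (adjusted p = 0.0601). Without cortex wild-type library 2 the cortex value was 0.29 with an adjusted p of 1.91e-05, and over all alternatives the adjusted p ranged from 1.91e-05 to 0.284. The difference between the tissues was -0.01 (adjusted p = 0.931). A predicted gene, Gm49227, overlaps App on the opposite strand.

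In cortex the clearest change in the knockout was a rise of genes known for their expression in striatal neurons. Drd2, the dopamine D2 receptor (ENSMUSG00000032259, chromosome 9, 49340627 to 49408177), rose from 165 ± 41.7 to 1347 ± 409 normalized counts (log2 3.01 ± 0.26, adjusted p = 0.00569), and Adora2a, an adenosine receptor, from 214 ± 67.7 to 1682 ± 539 (2.96 ± 0.29, adjusted p = 0.00723). Of the 19 tested genes in the list of striatal neuron markers, 16 rose, 0 fell and 3 were not called; adjusted over the list alone, 19 rose. The list had a median log2 fold change of 1.57 (camera adjusted p = 1.44e-25; adjusted p = 0.331 with an estimated correlation). Syndig1l, which the predicted gene Gm48573 overlaps on the opposite strand, rose by 2.79 ± 0.17 and Penk, the enkephalin precursor, by 1.89 ± 0.18. All 19 markers were also detected in wild-type cortex, at a mean of at least 10 normalized counts. Without wild-type library 2, which differed from libraries 1 and 3 with a chi-square per gene of 105 and 94.9 where those differed from each other with 9.40, the median was 1.53.

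**Figure D2:**
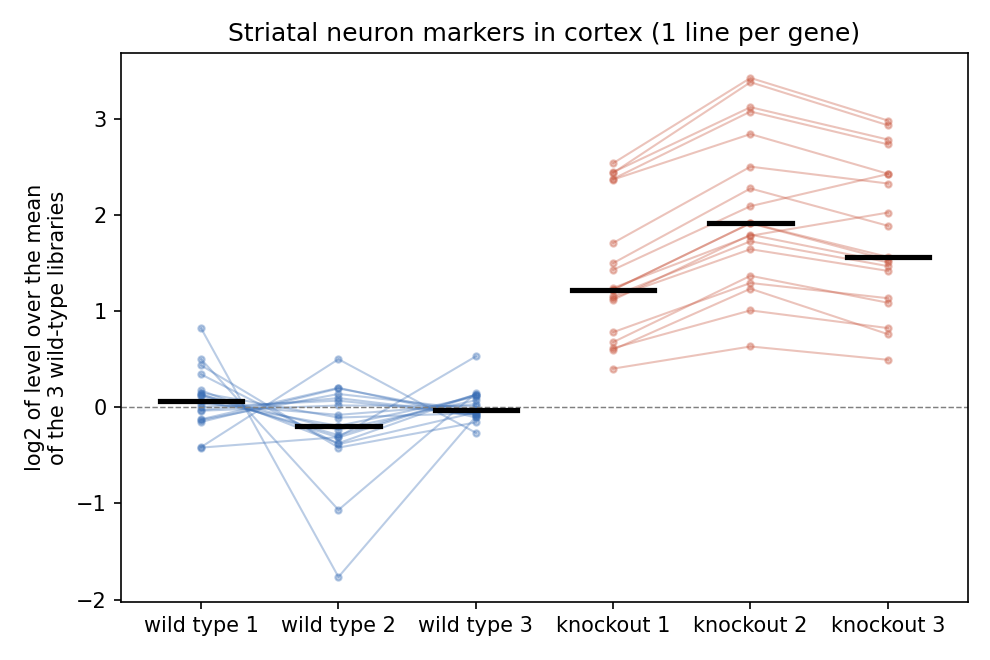
Level of 19 striatal neuron markers in the 6 cortex libraries (horizontal axis), as log2 of each gene's value over its mean in the 3 wild-type libraries (vertical axis), with 1 line per gene and black bars for the median. Every marker lies above its wild-type mean in each knockout library, and 17 of the 19 are highest in knockout library 2 and lowest in knockout library 1.

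The other large rises in cortex were Lrrc10b (237 ± 26.2 to 1816 ± 585 normalized counts), Sh3rf2 (44.7 ± 11.7 to 386 ± 118), Impg1 (log2 2.64 ± 0.39), and Serpina9 (24.8 ± 7.57 to 226 ± 57.6), which overlaps the predicted gene Gm28577. Lrrc10b, Sh3rf2, Impg1 and Serpina9 were each highest in knockout library 2 and lowest in library 1, as were 17 of the 19 striatal markers. The same order held for 20.3% of all tested genes, but not for Ptp4a1. A second gene model of the same name overlaps Ptp4a1, so its rise of 3.19 ± 0.18 is uncertain. Besides Tert, the largest falls were Nkain3 (-2.43 ± 0.43), Glp1r, the receptor of glucagon-like peptide 1 (-2.25 ± 0.27), Ctxn3 (-2.24 ± 0.38), C1ql2 (-2.20 ± 0.23), Aldh1a3, a retinoic acid-forming enzyme (-1.39 ± 0.23), and Zfp185 (-1.38 ± 0.17). Srrm4os, annotated antisense to Srrm4, fell by 2.18 on the log2 scale and is uncertain for that reason. The adjusted p-values of these 12 rises and falls lay between 0.00116 and 0.0446.

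In all, 426 of 21945 genes were called in cortex, 281 higher and 145 lower, with 74 and 60 of them changed by at least 1 on the log2 scale, and 71 of the 426 were predicted genes. All 426 had groups that did not overlap, as had 28.3% of all tested genes, against 10% by chance. The count depended on single libraries. It was 4693 without wild-type library 2 (425 of the 426 kept), 112 without wild-type library 1, 66 without wild-type library 3, and 63, 47 and 15 without knockout libraries 1, 2 and 3. With knockout library 3 left out, Drd2, Adora2a, Lrrc10b, Sh3rf2 and Serpina9 had adjusted p-values of up to 0.0648. The calls of Nkain3, Ctxn3, Srrm4os, Aldh1a3 and Zfp185 were lost without any 1 of the libraries other than wild-type library 2. Those of Glp1r and Impg1 were lost without 4 of the libraries and that of C1ql2 without wild-type library 3 or knockout library 3, while Tert, Ptp4a1 and Syndig1l were called in all 18 alternatives.

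Of the 38 lists, 14 passed in cortex. Several neuronal lists were higher, though hippocampal field markers were lower. In the excitatory neuron markers (median 0.16, adjusted p = 4.08e-05; adjusted p = 0.331 with an estimated correlation) 1 of 20 genes rose and 0 fell, and 5 rose and 1 fell adjusted over the list alone; Kcnv1 rose by 0.37 ± 0.07. GABA signalling (0.24, adjusted p = 4.11e-05; adjusted p = 0.611 with an estimated correlation) had 2 rises and 1 fall among 20, and 12 and 2 adjusted over the list alone. Gad1 and Slc32a1, which make and load GABA, rose by 0.36 and 0.34, and Gabrb1, a GABA receptor subunit, fell by 0.52. Gad1 and Slc32a1 are also in the list of inhibitory neuron markers, which did not pass in cortex (median 0.05, camera adjusted p = 0.757). The glutamatergic synapse list (0.15, adjusted p = 0.000480; adjusted p = 0.643 with an estimated correlation) had 0 calls among 40 genes by either adjustment, the second being adjusted over the list alone. Amyloid and tau genes (0.07, adjusted p = 0.0173; adjusted p = 0.331 with an estimated correlation) had 1 rise among 28, Mme, which encodes the amyloid-degrading enzyme neprilysin (0.81 ± 0.13), and 5 adjusted over the list alone; its median was 0.05 without wild-type library 2 or knockout library 2. Upper cortical layer markers (0.11, adjusted p = 0.0173; adjusted p = 0.611 with an estimated correlation) had 1 rise among 18, Rorb (0.62 ± 0.06), and 2 adjusted over the list alone; without wild-type library 2 the adjusted p was 0.114, without knockout library 1 it was 0.0522, and without wild-type library 3 the median was 0.17.

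Oligodendrocyte, endothelial, cholesterol synthesis and choroid plexus lists were also higher in knockout cortex. Astrocyte, oligodendrocyte precursor, microglia and mural cell markers did not pass there (medians -0.06, -0.05, 0.04 and 0.05). Oligodendrocyte markers (median 0.17, adjusted p = 1.01e-06; adjusted p = 0.414 with an estimated correlation) had 2 rises among 24 genes, Hapln2 (0.49 ± 0.06) and Enpp2 (0.49 ± 0.07), and 10 rises adjusted over the list alone. Endothelial markers (0.19, adjusted p = 0.000472; adjusted p = 0.331 with an estimated correlation) had 4 rises among 20, with Eng at 0.70, Slc2a1, the glucose transporter of the blood-brain barrier, at 0.51 and Slco1a4 at 0.53, and 7 rises and 1 fall adjusted over the list alone. Cholesterol synthesis genes (0.21, adjusted p = 6.03e-05; adjusted p = 0.331 with an estimated correlation) had 2 rises among 23, with Insig1 at 0.48 ± 0.08, and 6 adjusted over the list alone. Choroid plexus markers (0.66, adjusted p = 4.65e-06; adjusted p = 0.538 with an estimated correlation) had 2 rises among 20, Enpp2 and Clic6 (0.97 ± 0.17), and 6 adjusted over the list alone. Transthyretin, Ttr, the main choroid plexus transcript and chosen after its values were seen, measured 1928, 10183 and 6024 normalized counts in knockout libraries 1, 2 and 3 and 1054 ± 171 in wild type (adjusted p = 0.0955).

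A further 3 lists were lower in cortex. Meningeal and fibroblast markers had a median of -0.68 (adjusted p = 4.78e-09; adjusted p = 0.538 with an estimated correlation), with 1 fall among 22, Slc6a13 (-1.27 ± 0.20), and 8 adjusted over the list alone. Cytosolic ribosomal protein genes had a median of -0.23 (adjusted p = 7.00e-07; adjusted p = 0.673 with an estimated correlation), with 0 of 53 called by either adjustment, the second being adjusted over the list alone; without wild-type library 2 the median was -0.04. Hippocampal field markers had a median of -0.10 (adjusted p = 0.0173; adjusted p = 0.431 with an estimated correlation), with 3 falls among 27, Cpne7 (-0.66), C1ql2 and Lypd1 (-0.66), and 2 rises and 8 falls adjusted over the list alone. This call was lost without wild-type library 1 and without wild-type library 3, and the median was -0.20 and -0.05 without wild-type library 2 and knockout library 2.

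Genes of the circadian clock moved in both tissues. In cortex 5 of 18 rose and 0 fell (median 0.30, adjusted p = 4.08e-05; adjusted p = 0.511 with an estimated correlation), and 11 rose and 3 fell adjusted over the list alone. Ciart rose by 1.59 ± 0.12, Dbp by 1.10 ± 0.13 and Nr1d1 by 0.69 ± 0.10. In hippocampus 10 of 18 rose and 4 fell (median 0.30, adjusted p = 0.0342; adjusted p = 0.832 with an estimated correlation), as many as adjusted over the list alone. There Ciart, Dbp and Nr1d1, chosen after their values were seen, measured 1.19 ± 0.14, 0.95 ± 0.12 and 0.75 ± 0.06 and all rose, as did Bhlhe41 (0.54 ± 0.05), whereas Clock (-0.76 ± 0.04) and Per3 (-0.45 ± 0.04) fell.

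**Figure D3:**
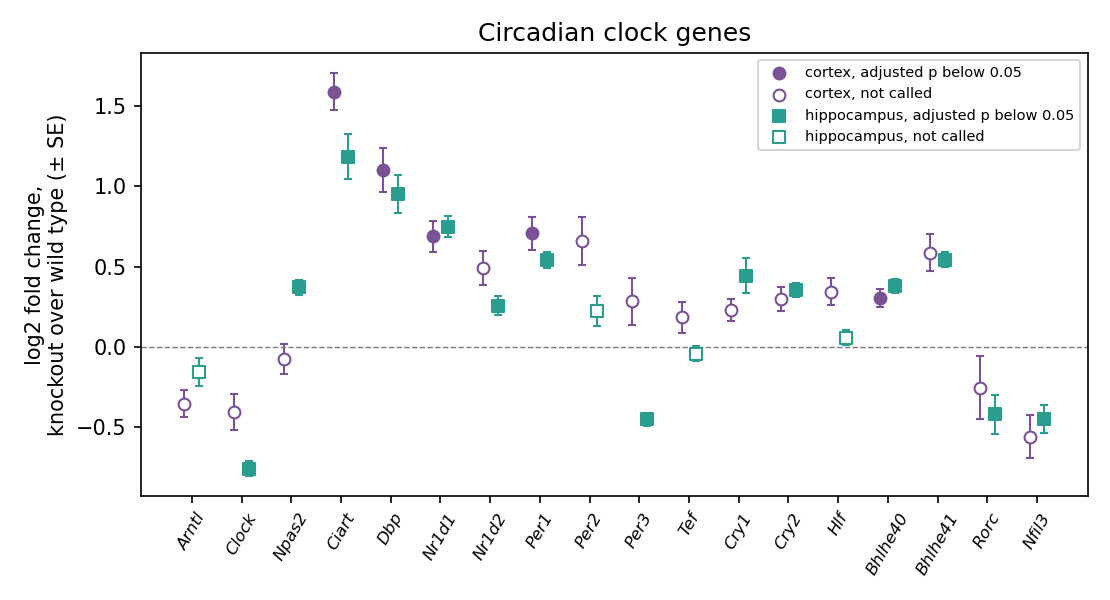
Log2 fold change, knockout over wild type (vertical axis), of 18 circadian clock genes (horizontal axis) in cortex (circles) and hippocampus (squares), with whiskers for SE and filled symbols for an adjusted p below 0.05. Ciart and Dbp are the highest points in both tissues, and Clock in hippocampus is the lowest at -0.76.

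In hippocampus most changes of at least 1 on the log2 scale in the knockout were falls. Hipk2, which encodes a homeodomain-interacting protein kinase (ENSMUSG00000061436, chromosome 6, 38694390 to 38876165), fell from 10238 ± 528 to 753 ± 102 normalized counts (-3.77 ± 0.10, adjusted p = 5.75e-06). Lcor, a nuclear receptor corepressor, fell from 1368 ± 96.2 to 84.7 ± 16.4 (-4.01 ± 0.14), and Kcng3, a modulatory potassium channel subunit, from 225 ± 22.2 to 14.4 ± 9.50 (-4.05 ± 0.40). Srcap, a chromatin remodelling ATPase that overlaps predicted genes, fell from 13467 ± 1394 to 1592 ± 888, and Anxa11os, antisense to Anxa11 and uncertain, from 129 ± 20.7 to 11.7 ± 0.945. Sult1c2 fell from 113 ± 92.1 to 8.73 ± 8.27, a call lost in 7 of 19 alternatives. In cortex Hipk2 measured 10260, 3120 and 9694 in wild-type libraries 1, 2 and 3 and 1598 ± 130 in knockout (adjusted p = 0.0603).

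The rises in hippocampus were smaller in number at this size. Skida1 rose from 232 ± 26.9 to 1391 ± 89.6 normalized counts (2.59 ± 0.10, adjusted p = 1.62e-05), Dlk1, an imprinted gene encoding a Notch ligand homologue, from 118 ± 30.6 to 384 ± 11.1 (1.73 ± 0.18), and Cd14, a coreceptor for lipopolysaccharide, from 64.2 ± 32.5 to 185 ± 2.19 (1.65 ± 0.35). Igha, the constant region of immunoglobulin A, rose by 2.42 ± 0.55 on the log2 scale and Lbhd2 by 1.58 ± 0.32. The mucin gene Muc5ac held 0 reads in each wild-type library and 3, 581 and 266 reads in knockout libraries 1, 2 and 3, a mean at least 83.1-fold higher with each wild-type library at the floor of 3 reads; its call was lost in 5 of 19 alternatives. Snurf (19.0 ± 27.5 to 309 ± 143) overlaps Snrpn, and Zc3h11a (1692 ± 937 to 5236 ± 2504) has a second model of the same name, so both are uncertain. The call of Igha was lost without knockout library 1 or 3, and that of Zc3h11a without knockout library 2 or 3.

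In all, 6513 of 22337 genes were called in hippocampus, 3141 higher and 3372 lower, 1392 of them predicted genes. Changes of at least 1 on the log2 scale numbered 125 upward and 1035 downward. Groups did not overlap in 6507 of the calls and in 45.8% of all tested genes, against 10% by chance. Rises made up 48.2% of the calls, but 60.7% after quantile normalization, which moved the median of all genes from 0.02 to 0.09, and 37.4% with no trend of the prior variance. The count test edgeR on recovered reads called 6682 genes, 6245 of them also called by limma in the same direction. Without wild-type library 3 the count was 3656, and without knockout library 2 it was 4069.

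The share of genes that fell in hippocampus differed with merged exonic length. Among protein-coding genes with more than 12 kb of exon, 614 of 865 fell (71.0%) and the median log2 fold change was -0.46. At 2 to 4 kb, 233 of 5019 fell (4.64%) and 1182 rose (23.6%), with a median of 0.10. Fold changes of the list members given below were not corrected for length, so they are not told apart from this pattern. Gene models annotated inside introns on the sense strand had a median of -0.37 over 103 genes in hippocampus and of -0.34 in cortex. In cortex, protein-coding genes with more than 12 kb of exon had a median of -0.05, with 12 rises and 6 falls among 866; against wild-type libraries 1 and 3 alone the median was -0.18 over the 863 of them tested in both tissues.

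**Figure D4:**
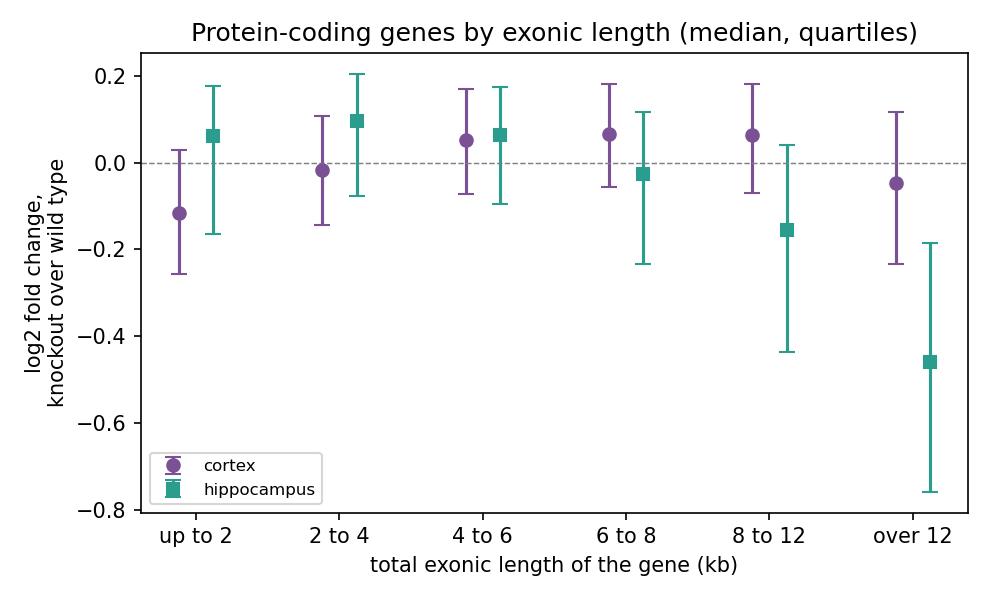
Log2 fold change, knockout over wild type (vertical axis), of protein-coding genes grouped by total exonic length in kb (horizontal axis), with medians as symbols and quartiles as whiskers. The median in hippocampus (squares) goes from 0.10 at 2 to 4 kb to -0.46 above 12 kb. In cortex (circles) it goes from -0.12 up to 2 kb to 0.07 at 6 to 8 kb, and then to -0.05 above 12 kb.

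Lists of the respiratory chain and ribosome were higher in knockout hippocampus. Short genes lay higher there as well. Protein-coding genes up to 2 kb of exon and at 2 to 4 kb had medians of 0.06 and 0.10, with 13.4% and 23.6% called higher. Of 45 nuclear oxidative phosphorylation genes 24 rose and 0 fell (median 0.13, adjusted p = 1.06e-08; adjusted p = 0.808 with an estimated correlation), and 30 rose adjusted over the list alone; Ndufs1 (0.30 ± 0.04) and Ndufv1 (0.29 ± 0.04), both of complex I, had the smallest p. Of 13 mitochondrially encoded genes 9 rose by either adjustment, the second being adjusted over the list alone (0.34, adjusted p = 0.000366; adjusted p = 0.832 with an estimated correlation), led by mt-Nd5 (0.62 ± 0.07). Of 53 cytosolic ribosomal protein genes 22 rose and 0 fell (0.11, adjusted p = 1.06e-08; adjusted p = 0.713 with an estimated correlation), 27 adjusted over the list alone, with Rps2 at 0.30, Rpl3 at 0.25 and Rpl4 at 0.22. Cholesterol synthesis genes (0.12, adjusted p = 0.0192, and adjusted p = 0.713 with an estimated correlation) had 7 rises and 1 fall among 23, and 11 and 1 adjusted over the list alone, with Sqle, squalene epoxidase, at 0.27 ± 0.04. Over the alternatives the median was as low as 0.07 for the ribosomal protein list and 0.08 for the cholesterol synthesis list. The nuclear oxidative phosphorylation and ribosomal protein lists each lost the call in 1 of 14 alternatives, the estimated correlation.

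Microglia markers rose in hippocampus, 17 of 22 with 0 falls (median 0.32, adjusted p = 3.17e-07; adjusted p = 0.832 with an estimated correlation) and 18 adjusted over the list alone. Itgam rose by 0.55 ± 0.05 and P2ry12, the microglial ADP receptor, by 0.69 ± 0.08. Oligodendrocyte markers (0.18, adjusted p = 0.000366; adjusted p = 0.832 with an estimated correlation) had 9 rises and 1 fall among 24, and 13 and 1 adjusted over the list alone, with Mag, a myelin adhesion protein, at 0.28. Astrocyte markers (0.14, adjusted p = 0.0312; adjusted p = 0.855 with an estimated correlation) had 8 rises and 2 falls among 20, and 9 and 2 adjusted over the list alone; Atp1b2 rose by 0.37 and Slc4a4 fell by 0.54. This call was lost without wild-type libraries 1 or 3 or knockout library 1, each left out singly.

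Neuronal lists were mixed in hippocampus. Excitatory neuron markers (median 0.22, adjusted p = 0.000625; adjusted p = 0.832 with an estimated correlation) had 11 rises and 0 falls among 20, and 13 and 1 adjusted over the list alone, with Ppp1r1a at 0.44 ± 0.05. GABA signalling (0.30, adjusted p = 0.00774; adjusted p = 0.852 with an estimated correlation) had 12 rises and 3 falls among 20, and 14 and 4 adjusted over the list alone; its smallest p belonged to Gabrb2, which fell by 1.86 on the log2 scale. Neurotrophin and memory signalling genes (0.16, adjusted p = 0.0378; adjusted p = 0.857 with an estimated correlation) had 12 rises and 5 falls among 30, and 14 and 5 adjusted over the list alone. Vgf rose by 0.42, while Creb1 and Adcy1 fell by 0.53 and 0.77, and the call was lost without wild-type library 1 and without wild-type library 3. The glutamatergic synapse list did not pass (median 0.11 but mean -0.05, adjusted p = 0.639), with 14 rises and 11 falls among 40, or 18 and 13 adjusted over the list alone; Grin2b, Pclo and Bsn fell by 0.92, 0.95 and 0.89. The falls of single genes in these lists were not corrected for exonic length.

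Choroid plexus and ependymal lists were lower in knockout hippocampus. The choroid plexus markers had a median of -2.35 with 0 of 20 genes higher (adjusted p = 0.000848; adjusted p = 0.855 with an estimated correlation), although the fall of Prlr (-2.97 ± 0.93) was the sole call and 0 were called adjusted over the list alone. Ttr measured 322269, 7986 and 165256 normalized counts in the wild-type libraries and 13343, 5087 and 8893 in the knockout libraries, so wild-type library 2 lay below knockout library 1. The list median was -1.42 without wild-type library 1 and -3.81 without wild-type library 2. Ependymal and ciliated cell markers (-0.51, adjusted p = 0.00774; adjusted p = 0.857 with an estimated correlation) had 4 falls among 20 by either adjustment, the second being adjusted over the list alone, with Hydin at -1.49, Dnah11 at -1.70 and Spata18 at -1.69; the call was lost without wild-type library 1 (median -0.23), and the median was -0.78 without wild-type library 2. The values of Hydin, Dnah11 and Spata18 were not corrected for exonic length.

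Near Tert on chromosome 13, 3 of 20 tested genes were called in hippocampus and 0 of 18 in cortex. Ccdc127, which is uncertain because Lrrc14b overlaps it on the opposite strand, fell by 0.35 ± 0.06, Sdha, a subunit of succinate dehydrogenase, rose by 0.19 ± 0.04, and Clptm1l, the gene next to Tert, rose by 0.17 ± 0.04. The calls of Sdha and Clptm1l were lost without wild-type library 3 or knockout library 2, and that of Clptm1l also without knockout library 1. The call of Ccdc127 was lost in 1 of 20 alternatives, over which its value ranged from -0.42 to -0.16. The Tert neighbourhood list passed in neither tissue (median 0.01 but mean -0.05 in cortex, adjusted p = 0.706, and median 0.04 in hippocampus, adjusted p = 0.679), with 0 calls in cortex and 2 rises and 1 fall in hippocampus adjusted over the list alone.

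Telomere maintenance genes did not pass the test against other genes in either tissue. In cortex 0 of 25 were called, also adjusted over the list alone (median -0.01, adjusted p = 0.519), and in hippocampus 3 rose and 7 fell (median 0.03 but mean -0.12, adjusted p = 0.679), or 4 and 8 adjusted over the list alone; Atrx fell there by 0.80 and Tep1, a telomerase-associated protein gene, by 0.99. The fry test, which asks whether a list moves on balance without comparing it with other genes, passed for this list in hippocampus (adjusted p = 0.0452). By fry, sex-linked genes (adjusted p = 0.0169) and upper cortical layer markers (adjusted p = 0.0162) passed there too, although neither passed camera. With 29.2% of all tested hippocampus genes called, such a pass is not particular to telomere genes. Of p53 target and DNA damage genes, 1 of 32 fell in cortex, Cdkn1a (-0.70 ± 0.12), also adjusted over the list alone, and 5 rose and 3 fell of 31 in hippocampus, or 4 and 3 adjusted over the list alone, with Atm at -1.24 ± 0.07. Neither test of that list passed (adjusted p = 0.311 and 0.731). The falls of Atrx, Tep1 and Atm were not corrected for exonic length. Interferon response genes had 0 calls in cortex and 2 rises and 2 falls among 33 in hippocampus (adjusted p = 0.992 and 0.196), with 0 and 1 calls adjusted over the list alone.

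Both tissues could be compared for 21282 genes. Across these genes, which are not independent replicates, the knockout effects correlated with Pearson's r = 0.378 and Spearman's rho = 0.246. Genes called higher in both tissues numbered 94, where independent lists would give 40.2, and genes called lower in both numbered 63, against 21.8. Genes higher in cortex and lower in hippocampus numbered 14, against 41.8, and the reverse held for 7. Without cortex wild-type libraries 1, 2 or 3, each left out singly, r was 0.250, 0.516 and 0.260.

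In the interaction test, 642 genes had a genotype difference that was not alike in the tissues. Of these, 205 had a higher and 437 a lower log2 fold change in hippocampus. The test does not tell an effect of the knockout from neighbouring tissue held by some of the samples. For the striatal markers this is taken up below. St8sia3, a sialyltransferase gene, measured 1.78 in cortex and -0.02 in hippocampus, a difference of -1.80 ± 0.11 (adjusted p = 3.75e-05). Syndig1l differed by -2.57 ± 0.20, the collagen gene Col11a1 by -1.62 ± 0.13, Tspan11 by -1.64 ± 0.15 and Ldb2 by 0.81 ± 0.08. Of the lists, 12 differed by camera, the striatal neuron markers most clearly (1.57 in cortex and 0.14 in hippocampus; adjusted p = 2.32e-17, and adjusted p = 0.390 with an estimated correlation). The number of genes depended on single libraries. It was 1332 and 1965 without cortex wild-type libraries 1 and 2, and 274, 186 and 187 without cortex knockout libraries 1, 2 and 3. It was 343 and 171 without hippocampus wild-type libraries 1 and 3, and 251, 188 and 195 without hippocampus knockout libraries 1, 2 and 3.

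**Figure D5:**
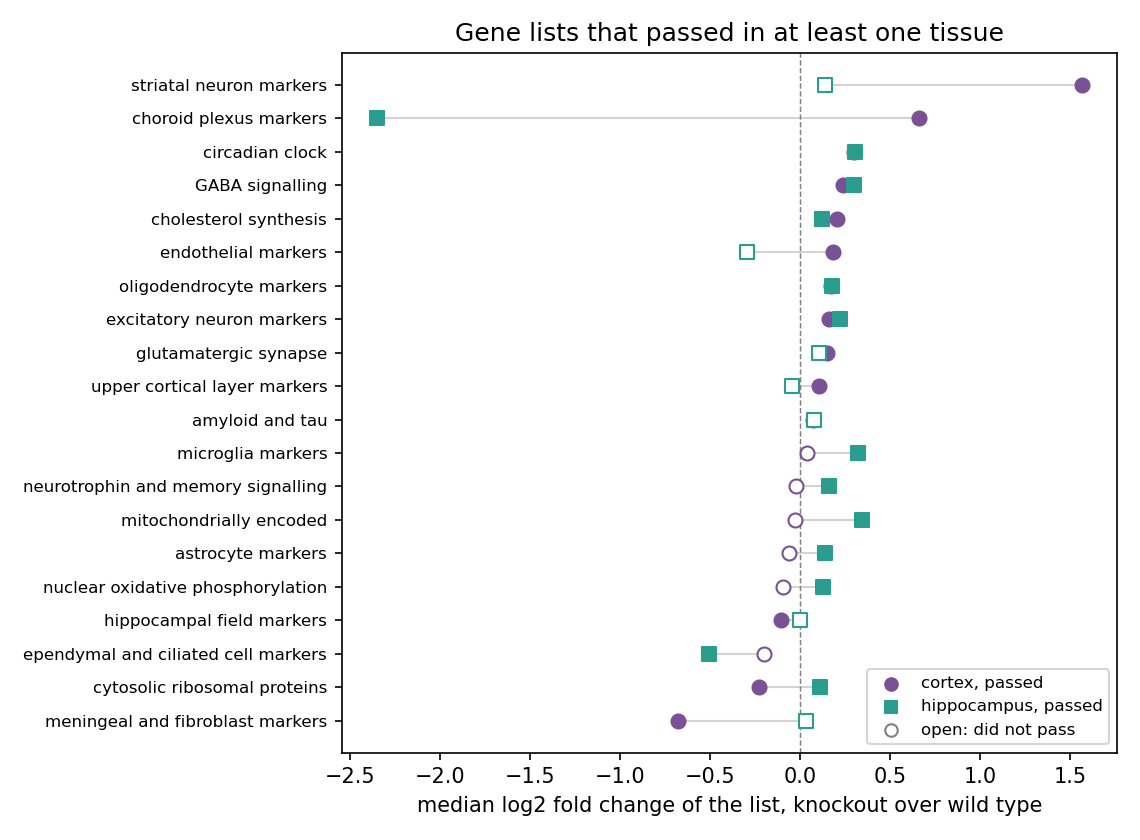
Median log2 fold change, knockout over wild type (horizontal axis), of the lists that passed in cortex (circles), hippocampus (squares) or both (vertical axis), with open symbols where the list did not pass. Striatal neuron markers lie at 1.57 in cortex and 0.14 in hippocampus, and choroid plexus markers at 0.66 and -2.35.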

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

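The tests on the order of the knockout libraries and the comparison of striatal with excitatory neuron markers were chosen after the result was seen. All values in this part were singled out because the knockout effect differed between cortex and hippocampus in the limma interaction test or, for lists, in camera on it; differences are hippocampus minus cortex on the log2 scale, with Benjamini-Hochberg adjusted p.

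Among genes named for cortex or for the interaction, the difference was -4.67 for Sh3rf2 (adjusted p = 0.0162), -3.25 for Drd2 (adjusted p = 0.00176), -3.39 for Adora2a (adjusted p = 0.00307), -2.81 for Lrrc10b (adjusted p = 0.000826) and -2.57 for Syndig1l (adjusted p = 0.000259). It was -1.80 for St8sia3, -1.62 for Col11a1 and -1.64 for Tspan11, with adjusted p of at most 0.000688. Others differed the other way, Glp1r by 2.62 (adjusted p = 0.00503), Ctxn3 by 3.38 (adjusted p = 0.0359), C1ql2 by 2.08 (adjusted p = 0.00307) and Ldb2 by 0.81 (adjusted p = 0.000688). Among genes named in hippocampus, Lbhd2 differed by 2.77 (adjusted p = 0.0135) and Srcap by -3.75 (adjusted p = 0.0212).

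Among lists, the median difference was -1.72 for striatal neuron markers (adjusted p = 2.32e-17; 0.390 with an estimated correlation). It was 0.23 for nuclear oxidative phosphorylation, 0.37 for mitochondrially encoded genes, 0.34 for cytosolic ribosomal proteins (whose cortex median was -0.23, or -0.04 without cortex wild-type library 2), 0.20 for astrocyte markers, 0.27 for microglia markers and 0.71 for meningeal and fibroblast markers. It was -0.39 for endothelial markers, -0.40 for mural cell markers, -3.09 for choroid plexus markers, -0.38 for ependymal and ciliated cell markers and -0.28 for upper cortical layer markers. The adjusted p of these 11 lists was at most 0.0397, and 0.759 for each with an estimated correlation. Mural cell markers, which passed in neither tissue, had medians of 0.05 and -0.33 (adjusted p = 0.166 and 0.234), with 1 rise among 16 in cortex and 2 falls in hippocampus, or 2 rises and 1 fall adjusted over the list alone.

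Of 100 drawn regroupings of the libraries within the tissues, 3 gave as many genes with a differing effect as the 642 of the real groups, the real one included. This excludes chance only for libraries without any genotype effect, not for a like effect in both tissues, since of 11 other regroupings that kept the hippocampus groups whole 2 gave as many. The highest other regrouping gave 3526, several times the real count, and the only other one above the real count gave 658. Both kept the hippocampus genotype groups whole, so the structure of the samples that they point to includes the hippocampus genotype difference itself.

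The rise of striatal neuron markers in knockout cortex may come from striatal tissue in the cortex samples, which would add its genes in 1 ratio. Of the 19 markers 17 were highest in knockout library 2 and lowest in library 1, among them the abundant Scn4b, Ppp1r1b, Adcy5 and Penk, as were 13 of the 15 held by no other list, 17 of the 20 choroid plexus markers and 20.3% of all tested genes. All 19 are also expressed in wild-type cortex, and 4 of the 20 listed genes are in another list. A general shift of neuronal RNA is argued against by the gap of 1.41 between the medians of the striatal and excitatory neuron lists. A striatal expression program raised by the knockout would share the library order among striatal markers too, though it would not by itself bring choroid plexus markers, and a biological difference between the genotypes stays open and untested.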

How the results depend on the processing

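Removal of the trends along length and GC content, and leave-one-out for the correlation, were added after the data were seen. Over all pairs of a named gene and an alternative, cortex genes kept direction and side of the threshold in 241, lost the call in 58 and gained it in 5; in hippocampus 360 kept it and 38 lost it, and the 5 genes named for the interaction kept it in all 80. Passing lists kept it in 170 in cortex and 151 in hippocampus and lost it in 26 and 31. No direction reversed.

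The cortex count of 426 became 233 with no filter on low values, 86 with no trend of the prior variance, 7358 with array weights (a fit that warned of incomplete convergence), 45 with the replicate block, 1562 in the joint fit of both tissues and 1275 with the length trend removed; leaving out single libraries gave 15 to 4693. Without the filter more genes were tested, and the joint fit has more samples; the cause was not tested for the others. The hippocampus count became 12907 with array weights and 3656 to 7833 with single libraries left out. The lists fell to 0 in each tissue with the estimated correlation, and to 8 in cortex with fry; the cause was not tested. The interaction count ranged from 171 to 1965 with single libraries left out. It was 515 with cortex and hippocampus libraries of the same genotype and number taken as a block. The correlation was 0.246 by Spearman and 0.250 to 0.516 with single libraries left out. Deviations of wild-type and knockout libraries of the same number correlated with r of -0.0649 to 0.00474 in cortex and -0.0266 to 0.0915 in hippocampus, so the numbers give no sign of pairing and the replicate block serves as a check. Count tests were not run for cortex or the interaction. Depth limits what values of 0 allow, up to 3 reads per library.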

Other observations

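The tests on exonic length, GC content and sense intronic gene models and both tests on cortex wild-type library 2 were chosen after the result was seen, and the genes in the next paragraph were chosen after their values were seen.

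The nuclear noncoding RNA Malat1 fell in both tissues, from 111356 ± 19455 to 57015 ± 4797 normalized counts in cortex (limma adjusted p = 0.0269) and from 137179 ± 15220 to 71004 ± 9795 in hippocampus (adjusted p = 0.000890). The imprinted noncoding RNA Meg3 fell by 0.46 on the log2 scale in hippocampus and had a value of -0.39 in cortex (adjusted p = 0.0777). Miat, another noncoding RNA, fell by 0.64 in hippocampus. In cortex its value of 0.25 (adjusted p = 0.507) rested on wild-type library 2. Wild-type libraries 1, 2 and 3 held 52785, 32376 and 52995 normalized counts there, and knockout 53549 ± 1877. S100a8, a calcium-binding protein gene of neutrophils, fell in both tissues (adjusted p = 0.0451 and 0.0226); wild-type cortex held 7.93, 97.2 and 31.6 normalized counts and knockout cortex 0 in each library. Clspn, a DNA replication checkpoint gene, rose by 1.92 ± 0.29 in cortex and by 0.83 ± 0.22 in hippocampus.

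Of the 10 splits of the 6 cortex libraries into 3 and 3, 1, the real one, gave 426 genes and the highest other gave 3; for the hippocampus libraries it was also 1, the real one with 6513, and the highest other gave 2. For lists the real values were 14 and 13 and the highest others 17 and 21, with 4 of 10 splits as high in each tissue, the real one included. With 10 splits no share under 0.05 can be reached.

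Protein-coding genes with more than 12 kb of merged exon had a median of -0.46 in knockout hippocampus, and 614 of 865 fell. Whether a trend along exonic length between libraries or the genotype underlies this cannot be told apart: removing the trend brought the median to -0.0282, but such removal centres long genes by construction, and the 3 knockout libraries all lay below the 3 wild-type ones (-0.21 to -0.25 against 0.18 to 0.27). For all 3372 fallen genes, of any length, the trend is argued against as the whole cause, since 2583 (76.6%) were still lower with it removed, against 273 of the 614 fallen protein-coding genes above 12 kb (44.5%). For those 614, a trend along GC content is argued against as the whole cause, with 585 still lower (95.3%). A like difference was also seen in 1 wild-type library. In cortex wild-type library 2, against libraries 1 and 3, the median was -0.46 over the 863 protein-coding genes above 12 kb tested in both tissues. It was -0.50 over the 3246 fallen genes also tested in cortex, so a difference between libraries that reaches beyond length is not excluded. Less nuclear or unspliced RNA in the knockout libraries stays open, as sense intronic models differed from protein-coding genes by -0.40, but by -0.35 in cortex too, where genes above 12 kb had a median of only -0.05 (-0.18 against wild-type libraries 1 and 3); an effect of the genotype is open and untested.

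Cortex wild-type library 2 differed from libraries 1 and 3 along exonic length (Spearman -0.562 across protein-coding genes, against 0.0988 for library 1 minus library 3). A knockout library under the wild-type label is argued against by its Tert value of 105 normalized counts, where the knockout cortex libraries had 0. Its difference from libraries 1 and 3 may be the length-related one that separates the hippocampus genotypes, as it correlated with the knockout effect there with r = 0.400 across 21282 genes, which are not independent replicates. No biological explanation was tested.

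A shifted clock phase between the genotypes may underlie the rise of clock genes in both tissues, a hypothesis tested on the genes of opposite phase. The median of Arntl, Clock and Npas2 was -0.35 in cortex and -0.16 in hippocampus, and that of 8 output genes 0.67 and 0.40. In both tissues these medians met the condition for a shifted phase that was set before the data were examined. The explanations are still held not to be told apart, on a ground outside that condition. In hippocampus Npas2 rose by 0.37 while Clock fell by 0.76, and Per3, an output gene, fell by 0.45. The hour of dissection is not given in the sources used here.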
